A study of Homo sapiens with 6 samples.

How the data were processed

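RNA of SH-SY5Y cells was sequenced in 6 libraries, 3 from cells expressing wild-type VPS35 (WT) and 3 from cells expressing VPS35 D620N, all after 7 days in 10 µM all-trans retinoic acid. Per the submitters' processing notes, the reads were handled with TopHat2 2.0.11 and Cufflinks 2.2.1 on the hg19 build. The junction files, 1 per library, hold as deposited the raw count of spliced read alignments across each intron, made with TopHat per the file headers and not normalized. No Cufflinks table was used here. The annotation, the read length, the strand setting and the treatment of reads with several placements are not given in the sources used here.

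A junction file counts reads that cross an intron. A gene was therefore measured by the sum of the spliced reads assigned to it, genes without introns were not measured, and a gene with many introns gathers more reads than a gene with few at the same abundance. The annotation at hand, GENCODE v29, is of another build, so coordinates were not carried over. Each annotated gene with at least 3 introns was named by matching the lengths and spacing of its introns to the introns in the files, on the same chromosome and strand, at 1 constant offset per gene. Introns of a gene that lie at another offset were not counted, so a gene can be measured by only part of its introns. Of 23389 such genes 13452 matched at 1 offset. After the data were examined, 51 genes were left out because none of the 5 neighbours on either side matched at an offset within 5000 bases, which left 13401 genes with a median of 11 matched introns. Another 65 genes with tied offsets and 1879 readthrough transcripts were also left out. When the genes were matched to the next chromosome instead, 1 of 23171 matched. The 6 libraries held 294281 distinct introns; 251154 were assigned to a gene by at least 1 annotated splice site, and 2652 that fitted more than 1 gene were left out. Between 84.8% and 92.0% of the junction reads of a library were assigned to a gene. Coordinates are those of the files, hg19, counted from 1.

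Counts per gene were tested with the quasi-likelihood test of edgeR 4.0.16 with TMM factors, a low-count filter of 10 reads (filterByExpr) and robust dispersions, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The standard error of a log2 fold change was derived from the fold change and its F statistic. Levels are given as CPM, the spliced reads of a gene scaled by the library's gene-assigned total and its TMM factor. Gene lists, 32 with 881 names, were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists. Where camera called a list, the same test with a correlation estimated per list stands beside it. Junction usage was tested with the edgeR function diffSpliceDGE in groups of junctions linked by a shared splice site. Library properties were compared with exact permutation tests, which cannot go below p = 0.1 for 3 against 3. R 4.3.3, igraph 2.1.4 and pandas 2.3.3 were used. Groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes VPS35, the 12 called genes with the largest fold change in each direction that have a mean of at least 50 reads and groups that do not overlap, the 6 called genes with the smallest p in each direction, and up to 4 members of a list that passes or has at least 3 called members, otherwise up to 2.

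Replicate numbers were taken to pair the libraries, because the series' design text ties replicates 1 to 3 to 3 independent experiments; it names no day or batch. Deviations from the group means, across genes, correlated by r = 0.033 for pair 1, 0.085 for pair 2 and 0.132 for pair 3, and each library correlated best with its own number; genes are not independent replicates. The main test had no block, and a fit with the replicate number as a block is an alternative. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.09 to 3.94 over genes, so each was counted as 1 replicate.

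Junction totals ran from 6529772 to 8963359 reads, and 3 reads corresponded to 0.366 to 0.503 CPM. The biological coefficient of variation was 6.31%. The tests were tested on simulated counts with the means and dispersions of these libraries and 200 changed genes. Of 50 genes per fold size, the gene test recovered 44.0% at 1.25-fold, 68.0% at 1.5-fold, 90.0% at 2-fold and 96.0% at 3-fold among 11383 genes, with 5 other calls. The 1.25-fold and 2-fold changes were all rises and the 1.5-fold and 3-fold changes all falls, so size and direction were not separated. Fewer genes were changed than the 1944 called in the data, which makes the adjustment stricter, so these rates are not the sensitivity of the real test. Among 2518 simulated junction groups the junction test recovered 0 of 67 junctions at 1.5-fold, 8.96% at 2-fold and 71.2% at 4-fold, with 0 other calls. The junction changed was the one with the fewest reads in its group. A list shifted 1.23-fold was recovered, with 0 other lists called. Genes were drawn independently, so this could not test false calls of lists whose genes vary together.

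Alternatives were other scaling factors, other low-count filters, DESeq2 1.42.0, limma-voom, limma's diffSplice, fry in place of camera, an estimated correlation, the replicate block, stricter junction filters, grouping of junctions by gene, stricter junction assignment, the junction with the most reads, thinning to equal depth, leaving out each replicate, and removal of trends with GC content, transcript length and intron number. The share of a gene's junction sequences, 30 bases on each side, that occur exactly in another gene was taken from the GENCODE transcripts. Genes on the Y chromosome and XIST, and the values of some other named genes, are not reported here. Wilson intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Bootstrap intervals resample the genes of a set, so they cover neither the spread between libraries nor the correlation between genes.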

Results

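Spliced reads were counted in SH-SY5Y cells, a human neuroblastoma line that takes on neuron-like features in retinoic acid. All cells had been kept for 7 days in 10 µM all-trans retinoic acid and expressed either wild-type VPS35 (WT, 3 libraries) or VPS35 D620N (3 libraries). VPS35 is the core of the retromer, which retrieves membrane proteins from endosomes, and D620N is a substitution known from familial Parkinson's disease. The comparison asks which RNAs differ between cells with the mutant and the wild-type protein. The series' design text gives 3 independent experiments, and the labels do not say whether the 2 lines were derived more than 1 time, so the p-values measure the spread between these experiments and not between lines. The WT libraries held 7315516, 6529772 and 6969668 junction reads, and the D620N libraries 8917682, 8963359 and 8385170. The D620N libraries were deeper, with a mean of 8755404 ± 321444 against 6938319 ± 393809 reads (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows, adjusted p = 0.2).

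VPS35 itself (ENSG00000069329.17, chromosome 16, minus strand, introns from 46694564 to 46723246 in hg19) was read at 1519.6 ± 92.2 CPM in WT and 1421.6 ± 29.8 CPM in D620N cells (SD, n = 3). The log2 fold change was −0.096 ± 0.047 (SE), which did not pass the test (edgeR adjusted p = 0.177). With the replicate number as a block it was −0.095 and passed (edgeR adjusted p = 0.0152), and without WT replicate 3 it was −0.15 (edgeR adjusted p = 0.031). Over the alternatives run for VPS35 (other scaling factors, DESeq2, the block and each replicate left out) adjusted p ran from 0.0152 to 0.555. Reads of a VPS35 cDNA and of the native gene cannot be separated in these counts, and the changed base is not visible in them. The first intron of VPS35, at 46717519 to 46723042, had 10.9 ± 0.717 CPM in WT and 11.2 ± 1.73 CPM in D620N cells. The remaining 15 introns had between 64.2 and 156 CPM in WT cells.

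**Figure D1:**
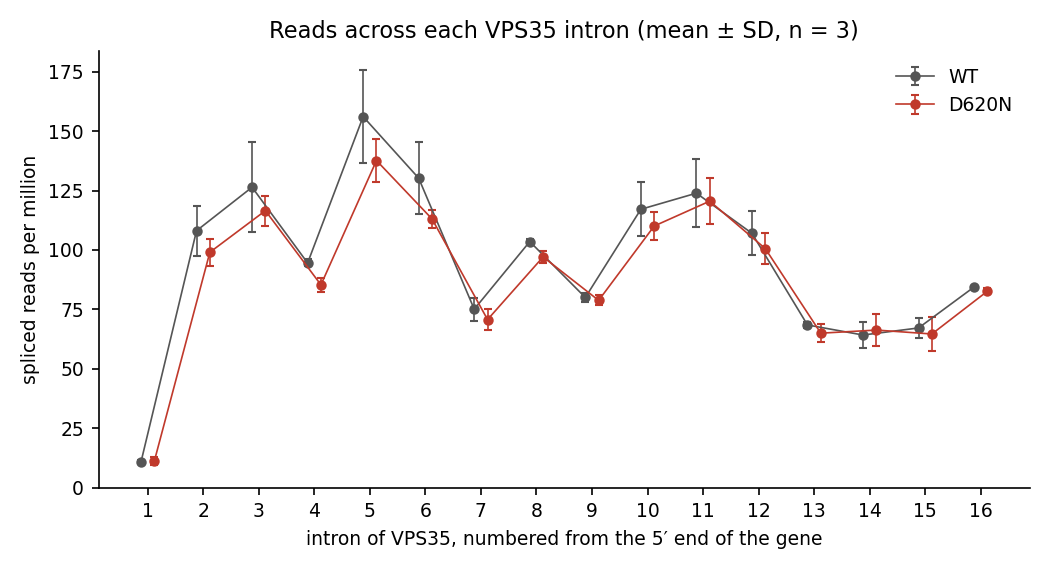
Spliced reads (CPM) across each of the 16 introns of VPS35, numbered from the 5′ end, as the mean of 3 WT (grey) and 3 D620N (red) libraries with SD bars. The first intron lies near 11 CPM in both groups, below the other introns.

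Of 11469 genes tested, 942 were higher and 1002 lower in D620N than in WT cells (edgeR quasi-likelihood test, adjusted p under 0.05). Most changes were small: the median absolute log2 fold change of the called genes was 0.354, and 130 genes rose and 201 fell by at least 1.5-fold. At 2-fold or more, 66 genes were higher and 38 lower. The groups did not overlap for 32.8% of the tested genes, against 10% by chance, and PC1, with 42.6% of the variance, separated the groups. With the replicate number as a block, 1409 genes were higher and 1521 lower. The counts fell to 486 higher and 539 lower without WT replicate 1, to 585 and 598 without WT replicate 2, and to 598 and 647 without D620N replicate 1. They were 190 and 241 when a gene was measured by its junction with the most reads.

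**Figure D2:**
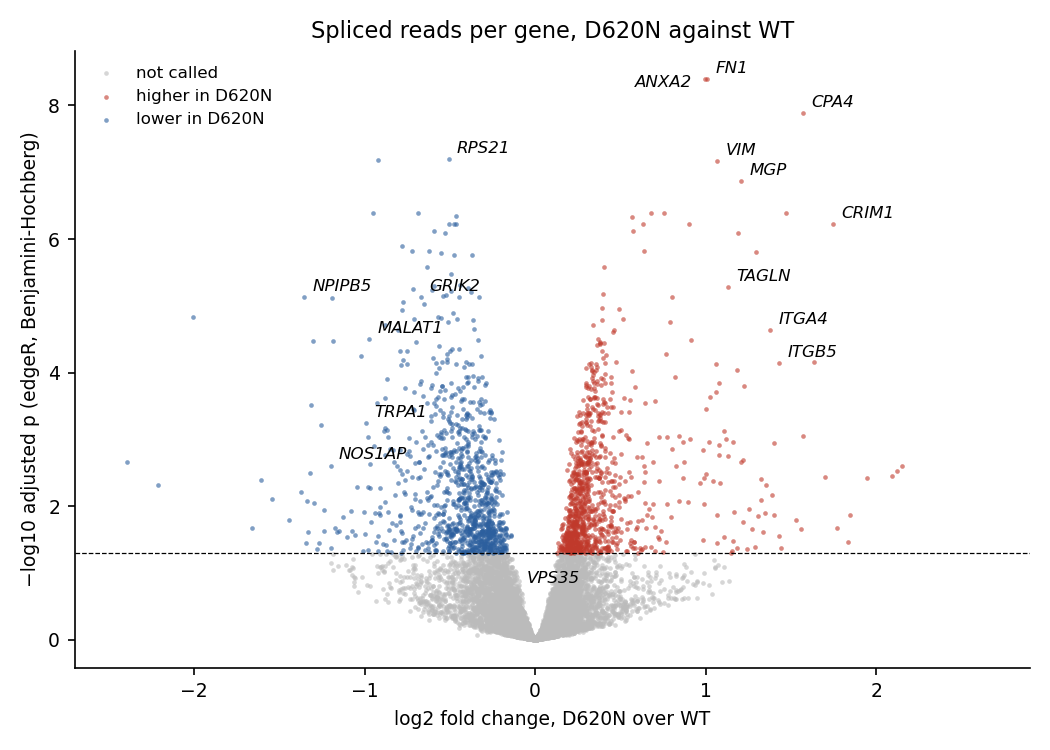
Each point is a tested gene, with its log2 fold change (D620N over WT) against −log10 of the edgeR adjusted p; the dashed line is the threshold of 0.05, red genes are higher and blue genes lower in D620N cells. CRIM1 lies at a log2 fold change of 1.75 on the right, and VPS35 lies below the line.

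CRIM1, a transmembrane protein with cysteine-rich repeats (chromosome 2, 36583767 to 36775667), rose from 8.67 ± 3.18 to 29.2 ± 1.28 CPM, a log2 fold change of 1.75 ± 0.17 (SE; edgeR adjusted p = 6.03e-07). CPA4, a carboxypeptidase, rose by 1.57 ± 0.11 on the log2 scale (adjusted p = 1.29e-08), and the integrin genes ITGB5 and ITGA4 rose by 1.43 ± 0.21 and 1.38 ± 0.18. The fibrillar collagen gene COL3A1 rose from 330 ± 80.0 to 826 ± 56.3 CPM, a log2 fold change of 1.32 (adjusted p = 0.00821; 0.057 without D620N replicate 3). Others among the 12 with the largest rise, of called genes with a mean of at least 50 reads and groups that did not overlap, were KRT18 (keratin; 1.47, with 42.9% of its junction sequences shared with other genes and so uncertain), MATN2 (matrilin; 1.29), PYGL (glycogen phosphorylase; 1.23), MGP (matrix Gla protein; 1.21), PLAT (tissue plasminogen activator; 1.19), FLNC (filamin; 1.18) and IQGAP2 (1.13). The smallest p-values belonged to ANXA2, an annexin, and FN1, fibronectin, at log2 fold changes of 1.00 ± 0.07 and 1.01 ± 0.07 (edgeR adjusted p = 3.99e-09 each). VIM, the intermediate filament vimentin, rose from 43.1 ± 4.40 to 90.4 ± 2.14 CPM (log2 1.07), and TPM1, a tropomyosin, by 0.76.

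Many of the named genes that fell belong to families with near-identical copies, so the counting could split reads between copies and their values are uncertain. NPIPB5, NPIPB13 and NPIPB3, of the nuclear pore interacting protein family, fell by 1.36, 1.30 and 1.19 on the log2 scale, and 88.6%, 94.4% and 96.2% of their junction sequences occur in other genes. The same limit holds for LINC01001 (−1.31), GTF2IP12 (−1.26), LRRC37A4P (−1.18), CSPG4P11 (−0.98), AC138035.1 (−0.98), LINC01347 (−0.95), SMG1P3 (−0.69) and GOLGA8A (−0.50), which share between 28.6% and 84.8% of their junction sequences. Among genes with few or no shared junction sequences, NOS1AP, an adaptor of neuronal nitric oxide synthase, fell from 12.6 ± 5.04 to 5.42 ± 1.21 CPM (log2 −1.20 ± 0.26; edgeR adjusted p = 0.00247). TRPA1, a cation channel, fell from 15.3 ± 2.01 to 7.72 ± 1.40 CPM (edgeR adjusted p = 0.000573), measured over 5 matched introns. Spliced reads of the non-coding RNA MALAT1 fell from 43.7 ± 2.52 to 22.4 ± 4.95 CPM (edgeR adjusted p = 3.16e-05). Unspliced MALAT1 RNA was not counted, so its total level is not known. LINC00265 (−1.02) and the pseudogene AC022905.1 (−0.92), with 16.7% and 4.17% of junction sequences shared, were also lower. The ribosomal protein gene RPS21 had the smallest p of the lower genes, at 3246 ± 44.0 CPM in WT and 2284 ± 53.5 CPM in D620N cells (log2 −0.51 ± 0.04; adjusted p = 6.43e-08), and RPS15A fell by 0.46.

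**Figure D3:**
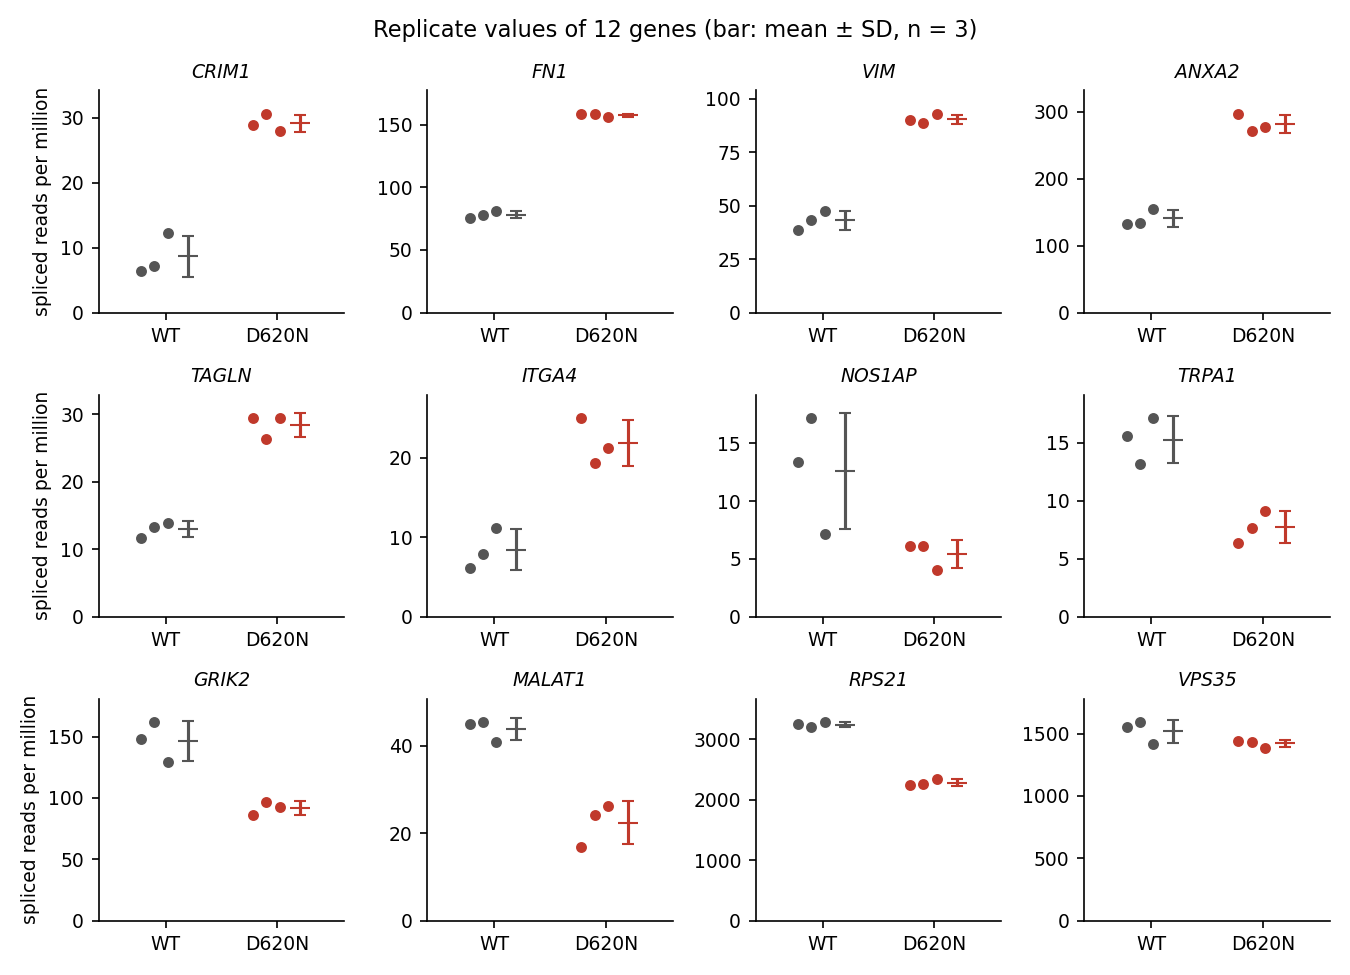
Spliced reads (CPM) of 12 genes in each library (points; grey WT, red D620N), with the mean and SD of 3 libraries beside them. CRIM1, FN1, VIM, ANXA2, TAGLN and ITGA4 are higher and NOS1AP, TRPA1, GRIK2, MALAT1 and RPS21 lower in all 3 D620N libraries, while the VPS35 groups overlap.

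The lists of extracellular matrix genes and of mesenchymal, substrate-adherent cells, a second cell form known in neuroblastoma lines, rose together. Of 28 measured matrix genes 19 were higher and 0 lower, with the same 19 when adjusted over the list alone (camera adjusted p = 2.02e-11; adjusted p = 0.238 with an estimated correlation). FN1, ITGA4, LAMC1 (laminin; log2 0.49) and ITGB1 (integrin; 0.33) had the smallest p. Of 16 measured mesenchymal markers 9 were higher and 0 lower, or 10 adjusted over the list alone (camera adjusted p = 2.24e-05; adjusted p = 0.238 with an estimated correlation). FN1 stands in both lists. VIM, the actin-binding TAGLN (log2 1.13 ± 0.13; edgeR adjusted p = 5.21e-06) and CALD1 (0.57) rose with it. Of 14 measured adrenergic neuroblast regulators, the other form of these cells, 1 was higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.478). TFAP2B (−0.44) and CCND1 (0.26) were among them, and with the replicate block 2 were higher and 2 lower. GATA3 (−0.52) was also lower, at an edgeR adjusted p of 0.0233. That p became 0.0509, 0.0558 and 0.0691 without WT replicates 1, 2 and 3, and 0.143 without D620N replicate 1. Of 4 measured Schwann and glial markers NES (nestin; 0.39) was higher and 0 were lower, the same adjusted over the list alone (camera adjusted p = 0.491).

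Lists of TGF-beta, interferon, Wnt and neurotrophin signalling rose in the same libraries as the mesenchymal list, whose median log2 fold change was 0.78. Of 12 measured TGF-beta and BMP genes 5 were higher, or 6 adjusted over the list alone, and 0 lower (camera adjusted p = 0.00113; adjusted p = 0.238 with an estimated correlation). LTBP1, a binding protein of latent TGF-beta, rose by 0.45 on the log2 scale. Of 15 measured interferon and inflammation genes 6 were higher, or 7 adjusted over the list alone, and 0 lower (camera adjusted p = 2.54e-05; adjusted p = 0.238 with an estimated correlation): HLA-C (0.87) and RELB (1.22) were among them. Of 17 measured Wnt pathway genes 3 were higher and 0 lower, the same adjusted over the list alone, with DKK2 (0.41) and CTNNB1 (0.21) first (camera adjusted p = 0.0411; adjusted p = 0.239 with an estimated correlation). The Wnt call ended with the replicate block (adjusted p = 0.0526), without WT replicate 1 (0.0595), WT replicate 2 (0.121) or D620N replicate 3 (0.107), and with trends of GC content, transcript length and intron number removed (0.0814). With those trends removed the median log2 fold change of the list was 0.24, against 0.26 before, with 3 genes higher and 0 lower. Of 17 measured neurotrophin and GDNF signalling genes 4 were higher, or 6 adjusted over the list alone, and 0 lower, against 7 higher and 1 lower with the replicate block (camera adjusted p = 0.0126, 0.0556 without D620N replicate 3; adjusted p = 0.315 with an estimated correlation). SORT1 (0.36), a sorting receptor, and KIDINS220 (0.23) had the smallest p. The calls of RET (0.15) and GFRA2 (0.42) ended without WT replicate 1 (edgeR adjusted p = 0.106 and 0.0931) or WT replicate 2 (0.106 and 0.102). Of 13 measured Notch pathway genes 0 were higher and 1, the ligand gene JAG2 (−0.48), was lower, the same adjusted over the list alone (camera adjusted p = 0.279), and 1 was higher and 2 lower with the replicate block. The edgeR adjusted p of JAG2, 0.0218, became 0.105 without WT replicate 2, 0.0524 without WT replicate 3 and 0.0827 without D620N replicate 2.

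Retinoic acid was present in both groups. Of 21 measured genes of its response 5 were higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.00762; adjusted p = 0.315 with an estimated correlation), and 7 were higher and 2 lower with the replicate block. CYP26A1, which degrades retinoic acid, rose from 495 ± 28.8 to 734 ± 42.1 CPM (edgeR adjusted p = 4.61e-07), and TGM2, a transglutaminase, by 0.90 on the log2 scale.

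Of 26 measured neurite and cytoskeleton genes 9 were higher, or 10 adjusted over the list alone, and 0 lower (camera adjusted p = 0.023; adjusted p = 0.315 with an estimated correlation). The tubulin genes TUBB3 (0.39) and TUBB2B (0.30) and the neuronal RNA-binding protein gene ELAVL4 (0.27) led it. That call ended without WT replicate 1 (camera adjusted p = 0.1) or D620N replicate 3 (0.111). In fry, which tests a list against no change and not against the other genes, the adjusted p was 0.0676. The lists of synapse genes had more lower than higher members and did not pass. Of 27 measured postsynaptic and channel genes 0 were higher and 9 lower, or 1 and 10 adjusted over the list alone, with a camera adjusted p of 0.0501 (adjusted p = 0.555 with an estimated correlation). The camera value became 0.0406 with the replicate block, 0.0478 with library totals, 0.0171 without WT replicate 3 and 0.041 without D620N replicate 3. With trends of GC content, transcript length and intron number removed it was 0.186, with 3 genes higher and 8 lower. The kainate receptor gene GRIK2 fell from 146 ± 16.4 to 91.9 ± 5.62 CPM (edgeR adjusted p = 7.47e-06), the scaffold gene DLG2 by 0.55, and the calcium channel genes CACNA1C and CACNA1D by 0.67 and 0.89 on the log2 scale. Of 33 measured presynaptic genes 1 was higher (SCG2; 0.65) and 6 lower, or 1 and 9 adjusted over the list alone (camera adjusted p = 0.101), and 10 were lower with the replicate block, with RIMS1 at −0.61 and SYNJ1 at −0.70. Of 23 measured axon guidance genes 3 were higher and 2 lower, or 3 and 3 adjusted over the list alone, 4 and 5 with the replicate block and 5 and 0 with those trends removed (camera adjusted p = 0.749), with SEMA3C at 0.77 and NRP1 at 1.33. The median of this list, −0.058, lies below 0, while its mean, 0.12, and the direction of its test lie above. Of 14 measured catecholamine genes 2 were higher and 0 lower, or 3 and 0 adjusted over the list alone and 3 and 1 with the replicate block (camera adjusted p = 0.478), among them CHGB (0.37). Of 10 measured cholinergic genes 0 were higher and 1, the muscarinic receptor gene CHRM3 (−0.57), was lower, the same adjusted over the list alone (camera adjusted p = 0.749). The edgeR adjusted p of CHRM3, 0.0258, became 0.201 without WT replicate 2, 0.0938 without D620N replicate 1 and 0.0515 without D620N replicate 3.

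**Figure D4:**
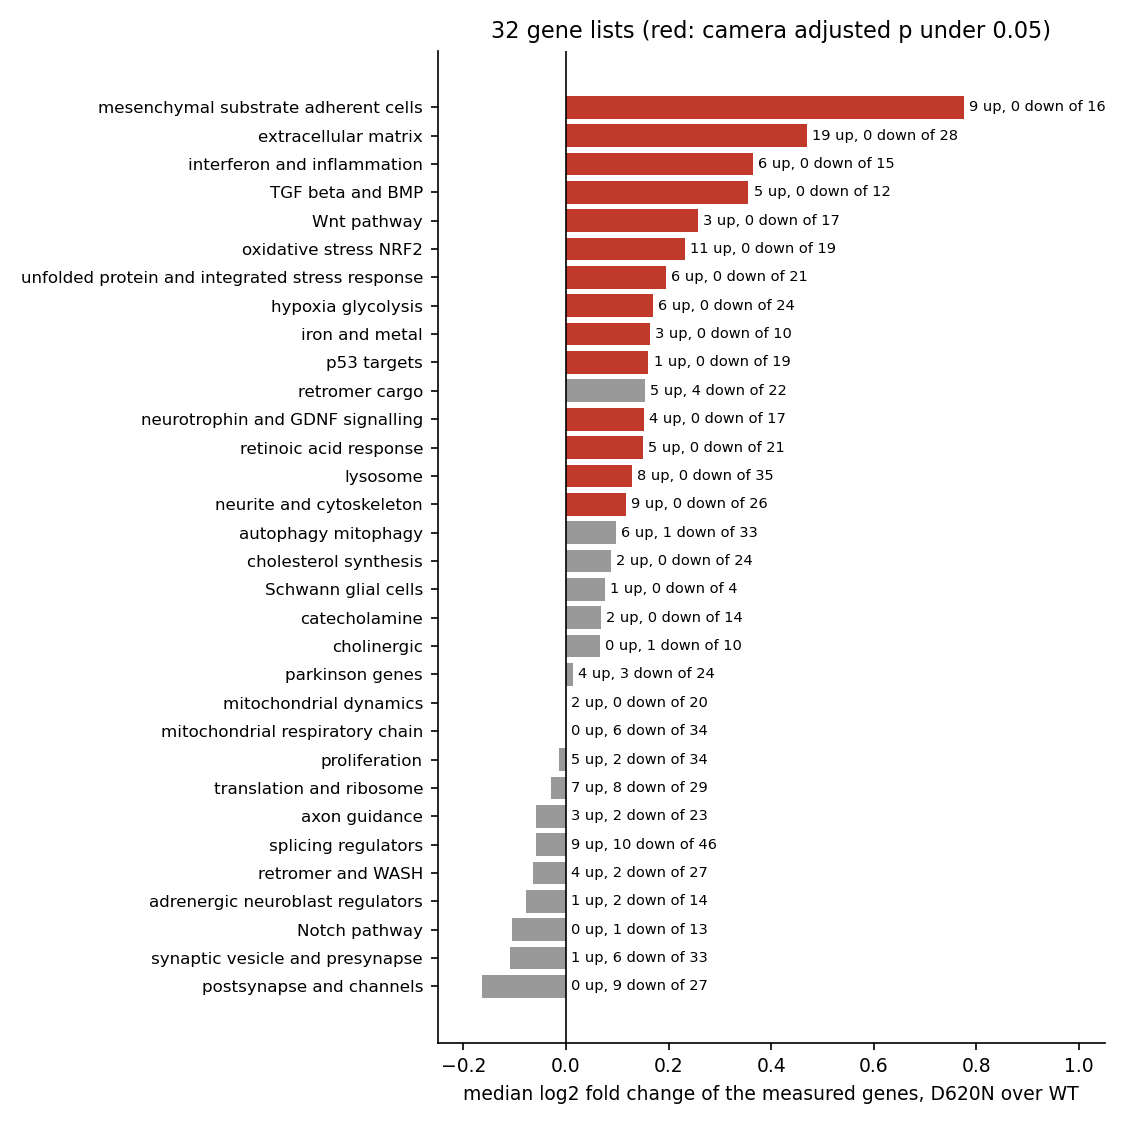
Median log2 fold change (D620N over WT) of the measured genes of each of the 32 lists, with the number of genes called higher and lower; red bars mark a camera adjusted p under 0.05 at the preset correlation. All 14 red lists lie to the right of 0, and the postsynaptic list has the lowest median, −0.16.

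The list of the retromer itself did not pass. Of 27 measured retromer and WASH complex genes 4 were higher and 2 lower, the same adjusted over the list alone, 4 and 5 with the replicate block and 4 and 1 with trends of GC content, transcript length and intron number removed (camera adjusted p = 0.92). CCDC93, of a complex that recycles endosomal cargo, fell from 122 ± 3.22 to 95.1 ± 2.21 CPM (edgeR adjusted p = 0.000997). The retromer subunit gene VPS26B rose by 0.43 on the log2 scale (edgeR adjusted p = 0.0197). That p became 0.0633 without WT replicate 1, 0.0884 without WT replicate 2, 0.0571 without D620N replicate 1 and 0.0515 without D620N replicate 2. WASHC5 and SNX2, each higher by 0.23, also lost their calls. Their edgeR adjusted p was 0.129 and 0.0995 without WT replicate 1, and 0.0815 and 0.0637 without WT replicate 2. Of 22 measured retromer cargo genes 5 were higher and 4 lower, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.0501; adjusted p = 0.238 with an estimated correlation). The camera value became 0.0359 without WT replicate 2, 0.0393 without WT replicate 3, 0.0345 after thinning to equal depth and 0.043 with those trends removed, and fry gave 0.0345. APP, the amyloid precursor, rose from 191 ± 11.4 to 255 ± 9.53 CPM, SORT1 by 0.36 and the copper transporter ATP7A by 0.34, and the glutamate receptor gene GRIA2 fell by 0.50. The APP value rests on 4 matched introns, from 27264181 to 27284052 on chromosome 21, and may leave out other introns of the gene. Of 24 measured genes linked to Parkinson's disease 4 were higher and 3 lower, or 4 and 4 adjusted over the list alone and 4 and 5 with the replicate block (camera adjusted p = 0.92). VPS13C, a lipid transfer protein, fell from 490 ± 42.1 to 357 ± 10.8 CPM (edgeR adjusted p = 1.55e-05) and SYNJ1 fell by 0.70 on the log2 scale. EIF4G1 and SCARB2 rose by 0.26 and 0.25. The median of the Parkinson list, 0.013, and the direction of its test lie above 0 and its mean, −0.016, below; the mean was 0.024 with those trends removed.

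Lists of lysosomal, oxidative stress, glycolysis, unfolded protein, iron and p53 genes rose in the same libraries as the mesenchymal list, whose median log2 fold change was 0.78. Of 35 measured lysosomal genes 8 were higher, or 10 adjusted over the list alone, and 0 lower, against 12 and 1 with the replicate block (camera adjusted p = 0.00136; adjusted p = 0.238 with an estimated correlation). PSAP (prosaposin; 0.39) and the membrane protein gene LAMP1 (0.44) had the smallest p. Of 33 measured autophagy and mitophagy genes 6 were higher and 1 lower, or 7 and 1 adjusted over the list alone and 8 and 3 with the replicate block (camera adjusted p = 0.101, fry adjusted p = 0.0222), including the autophagy receptors SQSTM1 (0.42) and NBR1 (0.38). Of 19 measured genes of the oxidative stress response 11 were higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.0006; adjusted p = 0.238 with an estimated correlation). TXNRD1 (0.40), a thioredoxin reductase, was among them, with TKT (0.42) and PGD (0.27), enzymes of the pentose phosphate pathway. Of 24 measured hypoxia and glycolysis genes 6 were higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.00134; adjusted p = 0.238 with an estimated correlation), with HK1 (0.47) and ENO1 (0.31). Of 21 measured genes of the unfolded protein and integrated stress responses 6 were higher and 0 lower, or 8 and 1 adjusted over the list alone and 9 and 1 with the replicate block (camera adjusted p = 0.0116; adjusted p = 0.238 with an estimated correlation). The chaperone gene HSP90B1 (0.30) and PDIA4 (0.36) had the smallest p. Of 10 measured iron and metal genes 3 were higher, or 4 adjusted over the list alone and 5 with the replicate block, and 0 lower, among them ATP7A and ACO1 (camera adjusted p = 0.0183, 0.121 without WT replicate 2; adjusted p = 0.238 with an estimated correlation). Of 19 measured p53 targets 1, the cell cycle inhibitor gene CDKN1A (0.72), was higher, or 0 adjusted over the list alone and 3 with the replicate block, and 0 lower (camera adjusted p = 0.0171; adjusted p = 0.238 with an estimated correlation). Over all genes 942 of 11469 were higher, so the p53 list held no excess of called genes. Its median log2 fold change was 0.16. The CDKN1A call (edgeR adjusted p = 0.0286) ended without WT replicate 1 (0.175), WT replicate 2 (0.0776), D620N replicate 1 (0.145) or D620N replicate 2 (0.0575) and with DESeq2 (0.0547).

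The remaining lists did not pass in camera. Of 34 measured respiratory chain genes 0 were higher and 6 lower, or 1 and 7 adjusted over the list alone and 2 and 7 with the replicate block (camera adjusted p = 0.514), with ATP5PO at −0.30 and COX7A2 at −0.27. Of 20 measured mitochondrial dynamics genes 2, YME1L1 (0.19) and OPA1 (0.18), were higher and 0 lower, the same adjusted over the list alone, 3 and 1 with the replicate block and 4 and 0 with trends of GC content, transcript length and intron number removed (camera adjusted p = 0.721). The edgeR adjusted p of YME1L1, 0.021, became 0.0631, 0.0651, 0.116 and 0.085 without WT replicates 1 and 2 and D620N replicates 1 and 2. That of OPA1, 0.0312, became 0.139, 0.0558, 0.0527, 0.0937 and 0.138 without WT replicates 1, 2 and 3 and D620N replicates 1 and 2, and its log2 fold change was −0.0077 in its junction with the most reads. Of 24 measured cholesterol synthesis genes 2 were higher and 0 lower, the same adjusted over the list alone, and 4 and 0 with the replicate block (camera adjusted p = 0.0871, fry adjusted p = 0.0197). They were DHCR7 (0.49) and PMVK (0.45), and the edgeR adjusted p of PMVK, 0.0197, became 0.137 without WT replicate 1 and 0.0574 without D620N replicate 2. Of 34 measured proliferation genes 5 were higher and 2 lower, the same adjusted over the list alone, 6 and 4 with the replicate block and 9 and 1 with those trends removed (camera adjusted p = 0.811). Of the 5, 4 were the replication licensing genes MCM2, MCM3, MCM4 and MCM6. The median of this list, −0.014, and its mean, −0.00064, lie below 0 and the direction of its test above, and the mean was 0.00097 with DESeq2 factors, 0.010 with library totals and 0.019 with trends removed. Of 46 measured splicing regulators 9 were higher and 10 lower, the same adjusted over the list alone (camera adjusted p = 0.491), with SRSF11 at −0.42 and HNRNPK at 0.24. Of 29 measured translation genes 7 were higher and 8 lower, or 7 and 9 adjusted over the list alone (camera adjusted p = 0.676): RPS14 fell by 0.46 and the elongation factor EEF2 rose by 0.40 on the log2 scale.

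Of 2784 groups of linked junctions 2 were called, and 46 had an unadjusted p under 0.05 (diffSpliceDGE in edgeR). Both lie in near-identical copies on chromosome 7, GTF2IP1 and GTF2IP4. Their junction reads were the same or nearly so in every library, so the 2 calls appear to count the same reads. The unannotated junction had 1, 0 and 0 reads in WT replicates 1 to 3 in both copies. In D620N replicates 1 to 3 it had 13, 14 and 14. In GTF2IP1 an unannotated intron from 74626314 to 74627797 took 0.0534 ± 0.0925% of the group's reads in WT and 1.44 ± 0.08% in D620N cells (SD, n = 3; edgeR adjusted p = 0.00796), next to the annotated intron that starts at 74626319. Of the groups that did not pass, SFPQ had a share of 78.7 ± 2.64% in WT and 88.6 ± 2.48% in D620N cells for the intron from 35650195 to 35652601 on chromosome 1 (edgeR adjusted p = 0.48). RPS24 had an edgeR adjusted p of 0.364. Both were called with junctions grouped by gene, where edgeR called 7 genes, and RPS24 was the 1 group called among those with at least 30 reads in 3 libraries. With the replicate block 0 groups passed in edgeR, with 52 at an unadjusted p under 0.05, and limma's diffSplice called 0, with 199. The count was 9 without WT replicate 1, 1 without WT replicate 2, 4 without WT replicate 3, 1 without D620N replicate 1 and 1 without D620N replicate 3, and 2 without D620N replicate 2. GTF2IP1 and GTF2IP4 were called without WT replicate 1 and in no other fit that left out a library. In simulated data the junction with the fewest reads of a group was changed. There 0 of 67 changes of 1.5-fold were recovered, 8.96% of those of 2-fold and 71.2% of those of 4-fold. Most changes of up to 2-fold in such junctions were therefore missed with these libraries, and depth was not varied.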

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

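Groups of 3 were too small for a test of outlying libraries. The values here concern reads outside the named genes, chosen after the data were examined: introns assigned to no gene that held over 1% of a library's junction reads, where the highest D620N library lay above the highest WT library. There were 3 such introns, all on chromosome 14 and 8935 bases long (hg19). The intron from 50320493 to 50329427 on the plus strand reached 3.33% (Wilson 95% interval 3.32% to 3.34%) of the reads of D620N replicate 2, against at most 1.63% in a WT library. It had 0 reads in D620N replicates 1 and 3 (Wilson upper limits 4.31e-05% and 4.58e-05%) and in WT replicates 1 and 3 (5.25e-05% and 5.51e-05%). The intron from 50320440 to 50329374 on the minus strand reached 2.87% (2.86% to 2.88%) in D620N replicate 3, against at most 0.00588% in a WT library and 0.00523% and 0.00105% in D620N replicates 1 and 2. The intron from 50320469 to 50329403 on the minus strand reached 6.94% (6.93% to 6.96%) in D620N replicate 3, against at most 0.929% in a WT library and 0.249% and 1.02% in D620N replicates 1 and 2. Another intron, from 50320464 to 50329398 on the plus strand, was highest in WT replicate 1 at 5.81% and had 0 reads in D620N replicate 3 (upper limit 4.58e-05%).

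Together the 4 introns took 6.74%, 2.78% and 3.85% of the reads of WT replicates 1, 2 and 3 and 2.81%, 7.09% and 9.81% of D620N replicates 1, 2 and 3. The Wilson 95% interval for D620N replicate 3 was 9.79% to 9.83%, which covers counting error alone. Reads across all introns recorded for this region made 4.48 ± 2.07% of the WT and 6.60 ± 3.53% of the D620N junction reads (SD, n = 3; exact permutation test, two-sided, p = 0.4, adjusted p = 0.533), a difference that did not pass. In GENCODE v29 the right ends of RN7SL3 and RN7SL2, genes of the 7SL RNA of the signal recognition particle on chromosome 14, lie 8935 bases apart, the same distance as the length of these introns. Their left ends lie 8934 bases apart. These reads were not part of the gene totals, and no explanation was tested.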

How the results depend on the processing

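Alternatives with gene-property trends removed, without genes that share junction sequences, and the thinned gene lists were added after the data were examined; the others were planned. Counts of called genes stayed within 1.5 times of 942 higher and 1002 lower with other scaling factors, other filters, DESeq2 (740 and 773), limma-voom, junctions annotated at both sites, thinning, removed trends (1304 and 943) and shared sequences left out (905 and 891). The replicate block gave 1409 higher and 1521 lower, holding 940 and 998 of the main calls, and the block with trends removed 1578 and 1178. The junction with the most reads gave 190 and 241, from fewer reads per gene. Leaving out 1 replicate gave 486 to 1000 higher and 539 to 1148 lower, with under 1/1.5 of the main count without WT replicate 1, WT replicate 2 or D620N replicate 1; fewer libraries are part of that. VPS35 passed with the block (−0.095) and without WT replicate 3 and ranged from −0.15 to −0.058 over the left-out replicates; adjusted p ran from 0.0152 to 0.555 over these and other scaling factors and DESeq2, the alternatives run for it. The ratio of total reads ranged from 1.23 to 1.30.

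With an estimated correlation 0 of 32 lists passed in camera (6 at an unadjusted p under 0.05), where camera at the preset value called 14 (17 unadjusted), fry 16 and left-out replicates 12 to 16; the cause was not tested. The paired fit ended the Wnt call, added the postsynaptic list and, among the named genes, TNFRSF10B (adjusted p = 0.0328), TFRC (0.00728) and NOTCH2 (0.012); apart from these, VPS35 and junction usage, it changed no call of the named genes or lists. Junction groups called were 1 at 30 reads or more (RPS24), 7 with junctions grouped by gene (RPS24 and SFPQ among them), 0 with limma, 0 with the replicate block, and 1 to 9 without 1 replicate (9 without WT replicate 1, 4 without WT replicate 3); the cause was not tested. Of 2643 checks of 141 named genes 2502 kept direction and call, 123 lost the call (53 of them with the junction with the most reads), 17 gained it and 1 reversed: OPA1, at −0.0077 in its junction with the most reads; the cause was not tested. Depth limits genes near 3 reads (0.366 to 0.503 CPM). Most simulated shifts of up to 2-fold in the junction with the fewest reads of a group were missed, at the 1 depth simulated.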

Other observations

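The gene types and ribosomal protein sets, and the tests of the share of mesenchymal cells, of the first intron of VPS35 and of chromosomes, were chosen after the result was seen; the other tests were set down before. Genes annotated as other than protein-coding fell: of 508 tested, 5 were higher and 104 lower, with a median log2 fold change of −0.23, against 937 higher and 898 lower of 10961 protein-coding genes (camera p = 8.09e-10, or p = 0.000976 with an estimated correlation, as a set chosen on these data). Of the 336 with no junction sequence found in another gene 2 were higher and 35 lower, so most of the lower calls were of genes that share sequences. Among all 508, 54 of 155 transcribed unprocessed pseudogenes, 17 of 106 lincRNA genes and 9 of 129 antisense genes were lower, and 2, 1 and 0 higher; antisense genes are uncertain because the strand setting is not known. Genes of small-subunit ribosomal proteins fell, with 18 of 31 lower and 2 higher (median −0.21; camera p = 7.58e-07, or p = 0.06 with an estimated correlation). Of 47 large-subunit genes 11 were lower and 3 higher, or 23 and 6 with the replicate block (median −0.083; camera p = 0.00191, or p = 0.347 with an estimated correlation). Both medians stayed below 0 with DESeq2 factors, library totals and removed trends.

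The rise of 43 extracellular matrix and mesenchymal genes, a median of 0.50 on the log2 scale above all tested genes, was 0.52 (95% bootstrap interval 0.29 to 0.79) once trends with GC content, transcript length and intron number were removed, and 0.49 (0.27 to 0.72) after thinning to equal depth. The value with trends removed argues against those trends as the whole cause. Thinning keeps each gene's expected share of the reads, so it could hardly move the median and does not decide on depth. A larger share of mesenchymal, substrate-adherent cells in the D620N line may contribute: the 14 adrenergic genes had a median of −0.078 (−0.34 to 0.094), an interval that includes 0, so this cannot be told apart from a change within cells. Of 31 named mesenchymal genes 16 were measured. COL3A1 (826 CPM), FN1 (157 CPM) and VIM (90.4 CPM), members of these lists, lay well above the floor in D620N cells. CPM sums the reads over a gene's introns, so these values do not rank abundance between genes. An effect of the D620N protein and a difference between the 2 lines that arose in culture both stay open, since the labels do not say how the lines were derived.

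The fall of non-coding genes and pseudogenes, −0.24 relative to protein-coding genes, was −0.21 (−0.23 to −0.15) for the 336 genes that share no sequence, −0.24 (−0.28 to −0.22) with trends removed and −0.24 (−0.28 to −0.21) after thinning. The values for unshared genes and with trends removed argue against shared reads and gene properties as the whole cause of the shift in the median. The thinned value could hardly have differed, for the reason given above, and does not decide on depth. A difference in RNA processing or in library preparation between the groups was not tested and may also give such a fall; the value for unshared genes, −0.21, does not separate them.

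For this comparison an intron was counted by all reads that enter the exon after it, from any start site. The first intron of VPS35 had 472 such reads over the 6 libraries against a median of 4181 for its other introns. The ratio was 0.113, where the median of 6754 genes was 0.685. The first exon of VPS35 is short, 62 bases, and the junction is 61.7% GC. Of the 200 genes nearest in these properties 21.0% had a lower ratio, but 19 of them had no first-intron read at all, so their 5th percentile was 0 and no ratio could have fallen below it; the test decides nothing. Only 3 coding bases lie in the first exon, fewer than the 8 that TopHat needs by default, so reads of a cDNA of the coding sequence may also be missed there. Neither explanation can be told apart from the other, and both lines had the same low level.

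With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1944 genes and 1 of 10 splits, itself, called as many, while the highest other called 0. Every other split mixes WT and D620N libraries in both groups, so a real difference adds to the spread within them. Their 0 is therefore not the number of genes expected by chance. The real split called 14 lists, as did 1 of 10 splits, and the highest other called 7 (WT replicates 1 and 2 with D620N replicate 1 or 2 called 6 or 7). For junction groups 5 of 10 splits called at least 2, the highest other 4. Replicate numbers were taken to pair the libraries, from the design text and not from their weak correlations; the 3 other splits that part all 3 such pairs called 0 genes, 0 to 4 lists and 2 junction groups each. Median log2 fold changes of 23 chromosomes ran from −0.049 to 0.051, all within 0.2 of 0, which argues against a gained or lost copy of a whole chromosome in 1 line.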
